A study of Arabidopsis thaliana with 2 samples.

How the data were processed

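Polyadenylated RNA of Botrytis-infected Arabidopsis leaves was sequenced in 2 libraries of 1 group, infected leaves at 24 h. Per the labels' protocols, RNA was extracted with TRIzol from 10 pooled leaves, purified on RNeasy columns and made into libraries with the Illumina mRNA-seq kit. The labels call the libraries technical replicates and do not name separate plants, so any spread between them is technical. Read names gave a different sequencing run for each library, so run and library cannot be told apart.

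The authors aligned the read pairs with Bowtie to TAIR10 transcripts and called bases with CASAVA 1.7.0 and 1.5.1, per the submitters' processing notes. The Bowtie version and options, any trimming, and which CASAVA version served which library are not given in the sources used here. The deposited values are Bowtie alignment lines (unit "other", neither read counts nor normalised values), with the transcript, the offset, the sequence of each 34-base mate and its mismatches. Each library has 2 such lists, an all-model list and a list for 1 representative model per gene. Checked on the lists themselves, 0 pairs stood in both lists of a library, every pair was listed with a single alignment, and mates lay within 250 bases. Of the 5745 genes in the representative lists, 5472 have several models in the reference annotation, and these held 99.4% of its pairs. Whether pairs that match several genes were left out or given to 1 of them is not given in the sources used here, so the levels of genes with near-identical copies are uncertain.

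Pairs were counted per gene over both lists of a library, which gave 10100701 pairs in replicate 1 and 16682699 in replicate 2. The planned count used the all-model list alone. It was replaced once the lists proved to be complementary, and the planned count is given as an alternative. Counts were scaled by the library total to CPM, and to RPKM, counted in pairs, with the length of the representative or most used model. Levels are therefore shares of the pairs placed on Arabidopsis transcripts. Reads placed on no Arabidopsis transcript are not part of the lists. Fungal pairs that match a conserved Arabidopsis transcript were not separated out. With 0 pairs, up to 3 pairs are allowed, or 0.297 CPM in replicate 1 and 0.180 CPM in replicate 2. Exact Clopper-Pearson intervals are at 95% and cover counting error only, since read pairs are not independent molecules.

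Gene symbols, products and lengths came from the TAIR10.1 RefSeq annotation, which held 21562 of the 21714 gene identifiers. Its models are not those of the authors, as 67.6% of 25749 models checked had the aligned sequence at another offset. Positions along transcripts were therefore measured against the largest aligned position. Symbols absent from that annotation are printed with their locus identifier. Organelle sites were placed by an exact match of at least 21 reference bases to the organelle genomes. As a measure of read sharing, each nuclear protein-coding model was given the percent of unique 34-base pair positions, at fragments of 122 and 225 bases. A position was unique when at least 1 mate was found in no other gene among these models. Organelle models were not part of this measure.

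Agreement was described by Pearson and Spearman coefficients across genes of log2(CPM + 1), with an interval from 1000 bootstrap draws of genes, and by the chi-square per gene. Genes with 50 or more summed pairs were compared between the libraries by an exact two-sided binomial test given the library totals, with Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05 and a log2 ratio of at least 1 in size, with 0.5 added to each count for the ratio. The 21 gene lists hold 270 genes. The median log2(RPKM + 1) of each list's members with a pair was set against 10000 random lists of the same size, drawn with replacement from nuclear genes with a pair. Between libraries the random lists were matched on expression in 10 bins. The two-sided share of random lists as far from their centre, adjusted over the lists by the Benjamini-Hochberg method and called past 0.05, describes these libraries only. Lists with fewer than 3 members were not tested.

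The groups, tests, thresholds, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 10 nuclear genes with the highest mean RPKM, the top 3 and lowest member of each list with up to 3 members without a pair, up to 5 genes in each direction between the libraries, up to 8 genes with the highest share on another model, up to 8 C-to-T sites and up to 4 genes with the highest share of mismatched pairs. Names outside it are marked as chosen after their values were seen. Of the genes that the rule names, 1 is not reported here.

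The tests were checked on simulated data made from the real gene means and totals, with counting noise only. The mean chi-square per gene was 1.01 there and 10.2 in the libraries, so the simulations do not give the rate of false calls in the libraries. With no gene changed, 0 of 14611 genes were called. In another simulation 200 genes were changed, drawn from the 14592 tested in the libraries. All 50 genes raised 3-fold and all 50 raised 5-fold in replicate 2 were called, as were 43 of 50 lowered 3-fold and 43 of 50 lowered 5-fold. Of the 14436 unchanged genes with 50 or more simulated pairs, 3 were called. Of 380 random lists of 12 genes 0 were called, and 20 of 20 drawn from the most abundant genes were. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

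Alternatives changed the alignment list, duplicate handling, mismatches, denominator, scaling, pseudocount, count minimum, length, background, share and coverage thresholds and the library used. Splitting reads over several genes could not be run, since each pair was listed at a single gene.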

Results

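The data were messenger RNA reads from leaves of Arabidopsis thaliana, accession Columbia-0, collected 24 h after infection with Botrytis cinerea, a necrotrophic fungus that kills host tissue and feeds on it. Leaves of 4-week-old plants had been detached and given 5 droplets each, and 10 infected leaves were pooled for RNA. A pair of libraries, called replicates 1 and 2 here, came from this time point of a longer series, and the series design describes them as technical replicates. Each SD below is therefore a technical spread over 2 libraries (n = 2), and no p-value below measures variation between plants. Uninfected leaves and the other time points were not analysed here, so levels are reported and no gene is said to be induced or repressed. Replicate 1 held 10100701 read pairs placed on Arabidopsis transcripts and replicate 2 held 16682699. They covered 20438 and 21018 genes, of which 19742 had a pair in both.

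The most abundant nuclear transcripts encoded glutathione S-transferases, a defence protein and enzymes of tryptophan and camalexin synthesis. GSTF2 ranked first at 6858 ± 1357 RPKM (SD, n = 2), followed by the predicted glycosyl hydrolase AT4G16260 at 5226 ± 209 and GSTF6 at 5113 ± 197. The pathogenesis-related gene PR4 stood at 4239 ± 476 RPKM and the N-acetyltransferase gene NATA1 at 4079 ± 690. TSA1 and TSB1, which encode the subunits of tryptophan synthase, reached 3978 ± 282 and 3682 ± 157 RPKM. PAD3, the cytochrome P450 of the last step of camalexin synthesis, reached 3837 ± 180, and EDA9, a phosphoglycerate dehydrogenase gene of serine synthesis, 3712 ± 144. The 10 most abundant nuclear genes together took 6.42% of the pairs of replicate 1 and 6.83% of those of replicate 2, and the 100 most abundant nuclear genes took 25.4% and 26.0%. Only 48.7% to 53.6% of the pair positions of GSTF2 were unique to it in the reference annotation, so its level is uncertain.

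In the TAIR10.1 assembly, GSTF2 (AT4G02520) lies on chromosome 4 from 1110343 to 1112033, and AT4G16260 on chromosome 4 from 9199972 to 9201643. GSTF6 (AT1G02930) lies on chromosome 1 from 661088 to 662475, PR4 (AT3G04720) on chromosome 3 from 1285425 to 1286760 and NATA1 (AT2G39030) on chromosome 2 from 16298110 to 16299205. TSA1 (AT3G54640) lies on chromosome 3 from 20223034 to 20225523 and PAD3 (AT3G26830) on chromosome 3 from 9887917 to 9889791. EDA9 (AT4G34200) lies on chromosome 4 from 16373731 to 16376666 and TSB1 (AT5G54810) on chromosome 5 from 22264594 to 22266902. All counted pairs lay on spliced transcript models.

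Every one of the 13 genes listed for camalexin and tryptophan synthesis was among the top 5% of nuclear genes. Camalexin is the main indole phytoalexin of Arabidopsis and is made from tryptophan. The list median was 1685 RPKM, and its members took 4.67% ± 0.0097 of all pairs (SD, n = 2). GSTF6, TSA1 and PAD3 led the list, and TSB2, the minor tryptophan synthase beta gene, was lowest at 199 ± 17.3 RPKM. None of 10000 random lists of the same size reached this median. The two-sided share of random lists as far out, called the adjusted share below after Benjamini-Hochberg adjustment over 20 lists, was 0.0004, and the smallest unadjusted share that these draws can give is 0.0002. On the representative alignments alone, where only 4 of its members had a pair, the list lay at percentile 97.24 and was not called.

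Genes of jasmonate synthesis and response were also high, as were the genes that mark the joint jasmonate and ethylene defence. All 27 jasmonate genes had pairs, 24 of them at 10 RPKM or more, with a median of 74.8 RPKM. JAZ1, a repressor of jasmonate signalling, stood at 713 ± 9.75 RPKM (SD, n = 2), the lipoxygenase gene LOX2 at 704 ± 48.3 and the acyl-CoA oxidase gene ACX1 at 551 ± 19.5, while the allene oxide cyclase gene AOC4 was lowest at 6.59 ± 0.78. Among the 13 defence markers, PR4 was followed by the ethylene response factor genes ERF1A at 437 ± 201 RPKM and ERF2 at 228 ± 10.99, and the defensin gene PDF1.3 was lowest at 7.49 ± 0.21. The spread of ERF1A came from 3548 pairs in replicate 1 against 11488 in replicate 2. Both lists lay above all 10000 random lists, with an adjusted share of 0.0004.

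Ethylene synthesis was split between a few abundant transcripts and near silence. ACO4 at 1587 ± 45.5 RPKM (SD, n = 2) encodes an ACC oxidase, which acts in the last step of ethylene synthesis, and ACS6 at 406 ± 18.6 and ACS2 at 83.4 ± 10.4 encode ACC synthases. ACS2 was chosen after its value was seen. Of the 12 genes, 8 were under 1 RPKM. ACO3 (AT1G12010) had 1 pair in replicate 1 and 0 in replicate 2, and ACS4 and ACS5 had 0 in both, which allows up to 0.297 CPM in replicate 1 and 0.180 CPM in replicate 2. The median of the 10 genes with a pair lay at percentile 1.11 of random lists, called low with an adjusted share of 0.030. The call did not hold: the list lay at 4.77 without replicate 1, at 5.15 on the all-model alignments alone and at 1.84 by CPM, none of them past the threshold, and with genes under 10 pairs left out its 6 remaining members were high, at percentile 99.99.

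All 16 salicylate genes had pairs. PR1, PR2 and PR5, commonly used as markers of salicylate responses, stood at 833 ± 70.3, 577 ± 35.1 and 138 ± 30.04 RPKM (SD, n = 2). Of the 16 genes, 3 reached 100 RPKM and NIMIN1 was lowest at 1.102 ± 0.21. The isochorismate synthase gene ICS1, the main entry to salicylate synthesis, stood at 5.52 ± 0.075 RPKM and was chosen after its value was seen. The list median of 23.5 RPKM lay at percentile 99.81, with an adjusted share of 0.0062. On the representative alignments alone, where only 5 of its members had a pair, the list lay at percentile 39.09, below the median of the random lists.

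Genes of pattern recognition and MAP kinase signalling, which detect microbes and relay the signal, had a median of 43.3 RPKM, with 19 of 20 at 10 RPKM or more. PROPEP3, the precursor of a danger peptide, stood at 188 ± 26.4 RPKM (SD, n = 2), the NADPH oxidase gene RBOHD at 144 ± 27.7 and the wall-associated kinase gene WAK1 at 142 ± 6.07. The flagellin receptor gene FLS2 was lowest at 3.93 ± 0.16. Among 15 WRKY transcription factor genes, WRKY75 reached 486 ± 124 RPKM, WRKY33, a regulator of camalexin synthesis, 439 ± 45.9 and WRKY40 295 ± 41.8, while WRKY18 was lowest at 6.45 ± 1.18. Both lists lay above all random lists, with an adjusted share of 0.0004. On the representative alignments alone the WRKY list, with only 3 members that had a pair, lay at percentile 96.9 and was not called.

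Senescence genes and genes of redox control and detoxification were abundant, and nuclear photosynthesis genes had a lower median. SAG13 stood at 1877 ± 45.7 RPKM (SD, n = 2), SAG21 at 1253 ± 100.2 and the transcription factor gene NAC019 at 373 ± 5.81, and ACD2, a gene of chlorophyll breakdown, was lowest of 15 at 7.29 ± 0.37. The redox list had a median of 402 RPKM, and 15 of its 18 genes were among the top 5%. After GSTF2 it was led by GSTF7 at 2813 ± 78.7 and the peroxidase gene PRX34 at 2696 ± 156. The catalase gene CAT2, the main leaf catalase of photorespiration, was lowest at 9.21 ± 0.088 RPKM, while CAT3, chosen after its value was seen, stood at 1367 ± 11.7. Of the 32 photosynthesis genes, 10 reached 100 RPKM, led by the Rubisco small subunit gene RBCS1A at 250.1 ± 3.69, LHCA4 at 218 ± 9.34 and LHCB1.3 at 217 ± 125, with RBCS1B lowest at 2.09 ± 0.59. The photosynthesis median was 57.6 RPKM, against 139 for senescence, a difference that was not tested, and all 3 lists lay above the random lists with an adjusted share of 0.0004. The near-identical members of the RBCS and LHCB1 families share sequence, and each pair was listed at a single gene, so the levels of these genes are uncertain.

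The glucosinolate list held both very high and very low members. PEN3, a transporter of the plasma membrane, stood at 905 ± 14.8 RPKM (SD, n = 2). CYP83B1 and SUR1, which act in glucosinolate synthesis, stood at 567 ± 111 and 471 ± 1.86. MYB29, a regulator of aliphatic glucosinolates, was lowest at 0.40 ± 0.079. Further members were chosen after their values were seen. The indolic regulator MYB51 stood at 332 ± 56.8 RPKM and the aliphatic genes MYB28, CYP79F1 and CYP83A1 at 1.76 ± 0.31, 2.85 ± 0.049 and 7.62 ± 0.59. The indolic regulator MYB34 was low as well, at 0.96 ± 0.17. Of the 16 genes, 8 reached 100 RPKM and the other 8 were under 10, and the list lay at percentile 99.98 with an adjusted share of 0.0011.

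In the phenylpropanoid list, the 10 genes of the general pathway and the lignin branch all stood at 10 RPKM or more, and the 6 flavonoid genes all stood below it. CAD5 stood at 574 ± 96.3 RPKM (SD, n = 2), CCOAOMT1 at 288 ± 27.7 and COMT1 at 268 ± 21.3, all enzymes of monolignol synthesis. The flavanone hydroxylase gene F3H was lowest, with 1 pair in replicate 1 and 11 in replicate 2. Chalcone synthase CHS, the first enzyme of the flavonoid branch, stood at 7.005 ± 0.95 RPKM and was chosen after its value was seen. The list of 16 lay above all random lists, with an adjusted share of 0.0004.

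Neither clock list stood apart from the random lists, whereas the reference genes were high. Of the reference genes, UBQ10 stood at 1569.9 ± 93.2 RPKM (SD, n = 2), GAPC1 at 722 ± 74.5 and the elongation factor gene EF1A (AT5G60390) at 639 ± 16.2, with TIP41L (AT4G34270) lowest at 10.6 ± 1.54. This list of 13 commonly used normalisers had a median of 97.9 RPKM and also lay above all random lists, so a high percentile is not particular to defence genes. The morning clock genes ran from PRR7 at 24.1 ± 2.13 RPKM, PRR9 at 4.25 ± 0.15 and RVE8 at 2.27 ± 0.31 down to LHY at 1.65 ± 0.20. The evening genes ran from GI at 23.5 ± 3.07, LUX at 21.7 ± 3.04 and PRR5 at 15.8 ± 0.056 down to ELF4 at 7.42 ± 1.72. The adjusted shares of the clock lists were 0.66 and 0.22.

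Guard cell markers were led by the potassium channel gene KAT1 at 22.3 ± 2.07 RPKM (SD, n = 2), with FAMA at 6.97 ± 0.38, SLAC1 at 2.57 ± 0.061 and HT1 lowest at 0.47 ± 0.063. Epidermis markers comprised KCS6 at 12.6 ± 1.52, ATML1 at 2.11 ± 0.023, PDF2 at 1.85 ± 0.24 and CER1 at 1.17 ± 0.10, and PDF1 (AT2G42840) had no pair. Vascular markers comprised the sucrose transporter genes SUC2 at 74.3 ± 18.5, SWEET12 at 70.8 ± 4.83 and SWEET11 at 54.2 ± 0.91 RPKM and the cellulose synthase gene IRX3 at 2.04 ± 0.041. The guard cell and epidermis lists did not pass the threshold, at adjusted shares of 0.46 and 0.57, and the vascular list was high at an adjusted share of 0.0060. On the all-model alignments alone the vascular list lay at percentile 95.3 and was no longer called.

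Markers of tissues outside the leaf gave almost no pairs. The 4 root markers, among them WER, EXPA7 and COBL9, had 0 pairs in both libraries. Pollen markers comprised ANX1 at 0.82 ± 0.020 RPKM (SD, n = 2), VGD1 with 1 pair in each library, HAP2 with 1 pair in replicate 2 and MGH3 with none. Seed storage markers comprised SESA1 with 2 pairs in replicate 1, CRU2 with 4 and OLEO1 with 1 in replicate 2, and 6 members, CRU1, CRU3 and SESA2 among them, with none. The pollen list was low at an adjusted share of 0.015, a call lost by CPM at percentile 1.65, and the seed list missed the threshold at 0.054, although a pseudocount of 0.1 brought it past at percentile 1.86. In all, 13 of 20 lists were high and 2 low. On the representative alignments alone 12 lists had enough members with a pair, and of the 10 of these that were called on both lists of alignments 7 kept their call. Root markers were not testable.

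**Figure D1:**
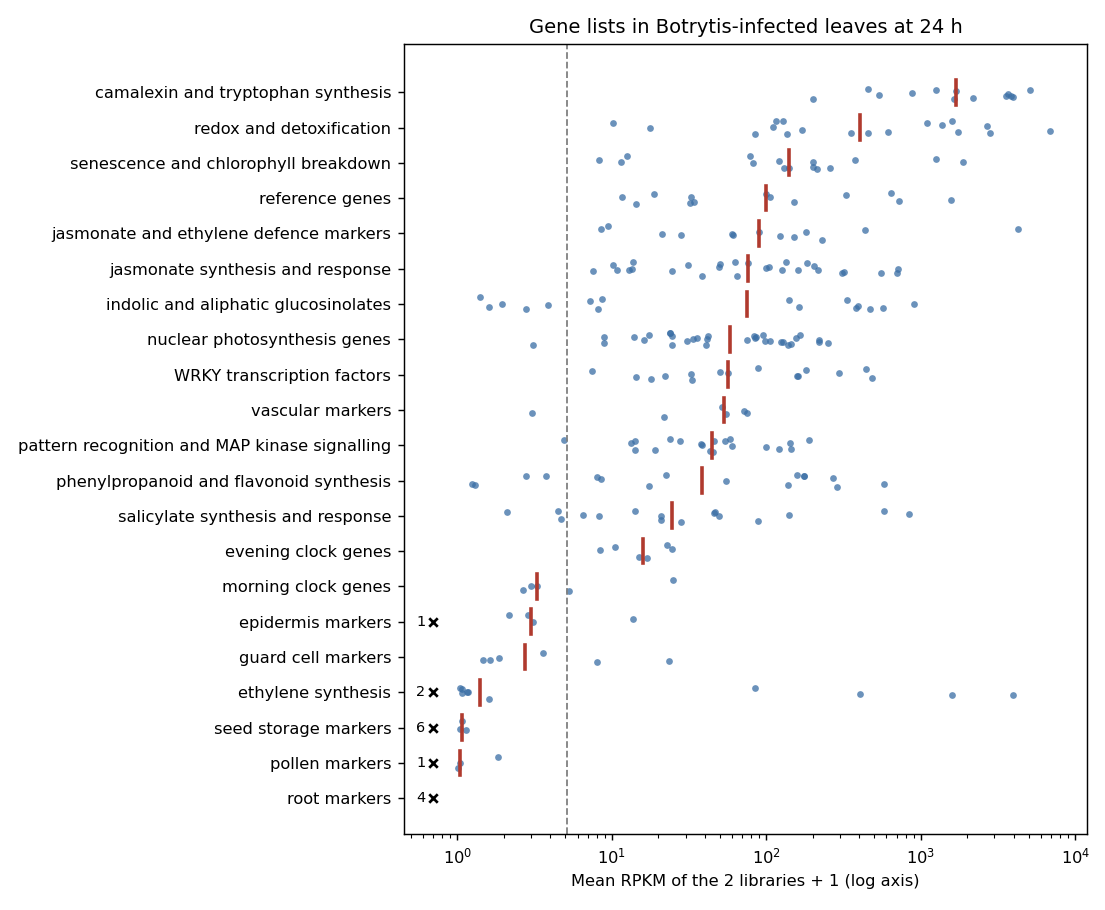
Mean RPKM + 1 of each member of 21 gene lists (points, log axis) over the 2 libraries, with the list median (bar), the median of all nuclear genes with a pair (dashed line) and the number of members without a pair (crosses). The camalexin and tryptophan list sits furthest right with a median of 1685 RPKM, and the 4 root markers had no pair.

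Whether the libraries agreed is the comparison that technical replicates allow. Across 21714 genes the log2(CPM + 1) values had a Pearson r of 0.992 (95% bootstrap interval 0.992 to 0.992) and a Spearman rho of 0.987. These are across genes, which are not independent replicates. Among 4627 genes with 1000 or more summed pairs, the SD of the log2 ratio of replicate 2 to replicate 1 was 0.27, and 96.3% differed by less than 1.5 times. The libraries nonetheless differed by more than sampling noise. The mean chi-square per gene was 10.2 (9.29 to 11.2), where sampling alone gave 1.01 in a simulation. The median was much lower, at 1.28, against 0.455 from sampling alone, so the mean does not describe the typical gene. The libraries were therefore counted as 2. Fragments were 122 bases at the median in replicate 1 and 225 in replicate 2, and 99.5% against 3.11% were under 150 bases.

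**Figure D2:**
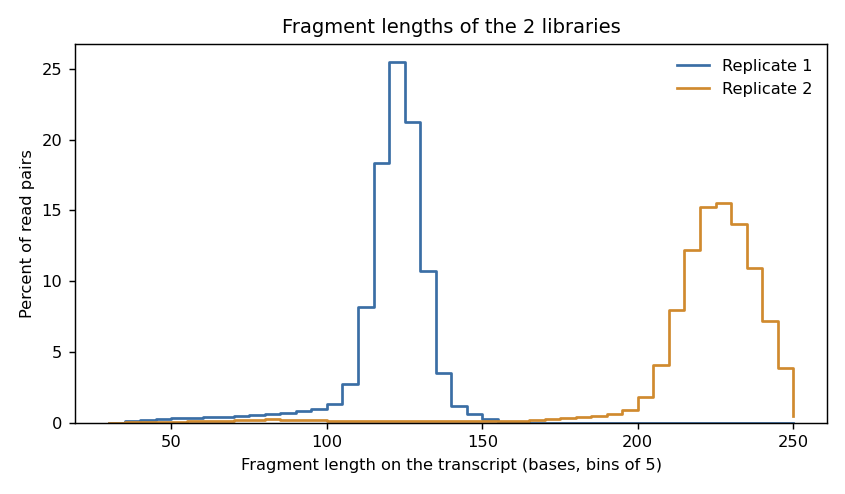
Percent of read pairs (vertical axis) by fragment length on the transcript in bases (horizontal axis, bins of 5 bases) for replicate 1 and replicate 2. The medians are 122 and 225 bases, and the distributions barely overlap.

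The genes that differed most between the libraries included organelle genes and short transcripts. The largest deficits in replicate 2 were those of the mitochondrial transcript ATMG00030, with 216 pairs in replicate 1 and 5 in replicate 2 (log2 ratio -6.02, replicate 2 over replicate 1), the non-coding RNA AT1G35545, with 206 and 6 (-5.71), and the photosystem II gene psbE (ATCG00580), with 74 and 3 (-5.14). They were followed by the ribosomal protein genes rps14 (ATCG00330) of the chloroplast, with 374 and 37 pairs (-4.04), and AT3G56020, a nuclear L41 gene, with 266 and 27 (-4.001). Pairs on ATMG00030, psbE and rps14 reached no further than base 183, 250 and 301, and the median fragment of replicate 2 was 225 bases. The deficits of these short stretches therefore cannot be told apart from an effect of fragment length. AT1G35545 and AT3G56020 had 814 and 522 bases by model length, the larger of the annotated length and the largest aligned position. The annotated models are not those of the authors, so these lengths do not set the 2 deficits apart from an effect of fragment length. The largest excesses were those of AT5G51680, with 6 and 59 pairs (2.47) and only 11.6% to 12.6% of its pair positions unique to it in the reference annotation, AT1G20390, with 8 and 66 (2.24), and the chloroplast RNA polymerase gene rpoB (ATCG00190), with 7 and 57 (2.21). AT1G59124, a disease resistance gene with no unique pair position in the reference annotation, and AT2G07671, an ATP synthase subunit gene, each had 11 and 82 (2.12). Organelle models were not part of the uniqueness measure, so sequence that AT2G07671 may share with an organelle gene would not show. Of 14592 genes with 50 or more summed pairs, 226 differed by at least 1 on the log2 scale at an adjusted p under 0.05 by the exact binomial test with Benjamini-Hochberg adjustment, 68 of them higher and 158 lower in replicate 2. Of 33 organelle genes tested, 20 were among the lower and 3 among the higher. At any size, 4068 genes passed. This compares the 2 libraries and not conditions and has no replicate check. The all-model alignments alone, the count planned before the data were seen, gave 794 such genes, 583 higher and 211 lower, of which 181 were among the 226. Fragments under 150 bases in both libraries gave 803, of which 663 were higher and 140 lower. Most calls there were thus higher in replicate 2, but on other genes, since only 40 were among the 226.

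Of the 236 listed genes with 50 or more pairs, only LHCB1.3 and PDF1.2a passed that threshold over all genes tested, and the same number, 2, passed when adjusted over the list alone. LHCB1.3, a light-harvesting gene, had 1600 and 6283 pairs (log2 ratio 1.25), and the defensin gene PDF1.2a, chosen after its value was seen, had 1015 and 676 (-1.31). The median transcript length was 761.5 bases for the genes lower in replicate 2 and 1431.5 for the higher ones, both below the 1745 of all tested, and the median GC content was 39.0% and 43.5%, against 41.6%. Across genes the log2 ratio rose with transcript length (Spearman rho 0.26) and with GC content (0.34). Its median went from -0.27 in the shortest of 10 bins of genes to 0.07 in the longest, and from -0.23 in the lowest bin of GC content to 0.15 in the highest.

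**Figure D3:**
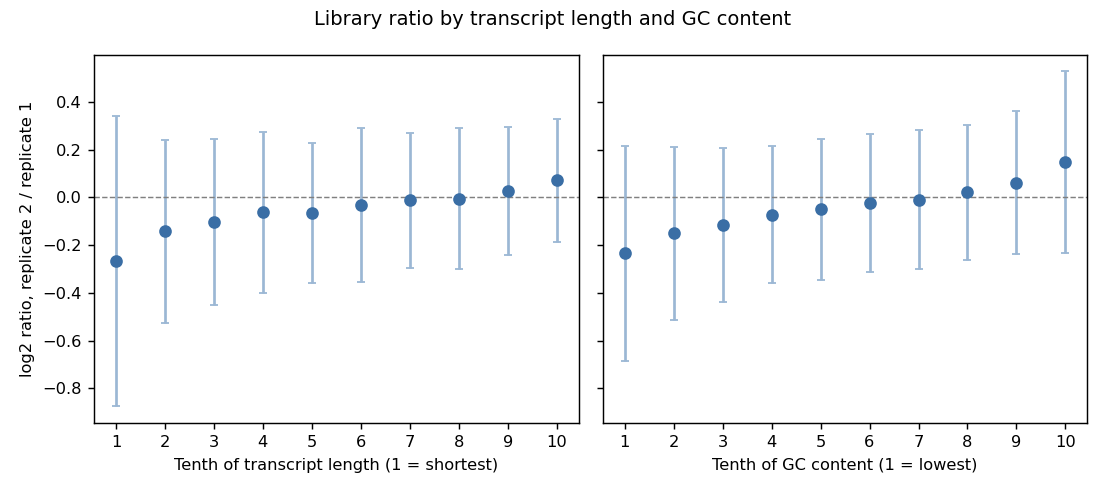
Median log2 ratio of replicate 2 to replicate 1 (points) with the SD over genes (bars) in 10 bins of transcript length (left) and of GC content (right), for genes with 50 or more summed pairs. The median goes from -0.27 to 0.07 with length and from -0.23 to 0.15 with GC content, within SDs of 0.26 to 0.61.

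Only 1 of the 18 gene lists with enough members stood apart between the libraries. Nuclear photosynthesis genes were higher in replicate 2, with a median log2 ratio of 0.18 over 32 genes, above all of 10000 random lists matched on expression, with an adjusted share of 0.0036. These random lists were not matched on transcript length or GC content, with which the ratio changed. The WRKY list had a median of -0.21 over 15 genes, at percentile 0.37, and missed the threshold with an adjusted share of 0.068. The other 16 lists had adjusted shares from 0.79 to 0.88. On the representative alignments alone only 10 of the 32 photosynthesis genes had enough pairs, and these were not called, at a median of 0.047 and an adjusted share of 0.91. On the all-model alignments alone 3 lists were called, the photosynthesis list, the jasmonate list at 0.21 and the WRKY list at -0.26.

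The authors deposited 2 alignment lists for each library, and the comparison shows how many genes cannot be counted from the all-model list alone. Pairs on a single gene model stood in the all-model list, and 29.6% of the pairs of replicate 1 and 27.6% of those of replicate 2 stood only in the list for representative models. With both lists summed, 3882 of 11996 genes with 50 or more pairs in replicate 1 rose above 1.5 times their count on the all-model list, and 4188 of 13290 did in replicate 2. In 881 and 587 genes every pair stood in the representative list. The genes named above by level show what this changes. On the all-model list alone the RPKM of UBQ10 was 0.598 in place of 1569.9, that of EF1A 1.91 in place of 639, that of SAG13 28.1 in place of 1877, that of GSTF6 1270.1 in place of 5113 and that of JAZ1 179.7 in place of 713. Of 82 genes named for their level, 79 had a pair on that list, and 17 of these were over 1.5 times lower there, with levels scaled by the smaller total of that list. The other 3, F3H, LHY and CER1, had no pair there. Among genes of the list for representative models, 16.9% of pairs in replicate 1 (exact 95% interval 16.9% to 17.0%) and 20.2% in replicate 2 (20.2% to 20.3%) stood in the all-model list, each specific to a single model.

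Model-specific pairs pointed mainly to a model other than the representative in 224 of 1029 genes with at least 50 such pairs in each library. In 63 of these genes the share was 100% in both libraries. Among them were the efflux carrier gene DTX35 with 661 and 675 such pairs, the nuclear transport factor gene NTF2B with 480 and 817, the synaptobrevin-related gene SAR1 with 301 and 988, and NOI, a gene of the RIN4 family, with 157 and 1030. AT1G25098 (350 and 771), the adenine nucleotide transporter gene ADNT1 (361 and 744), AT2G33710 (346 and 754) and AT4G00300 (319 and 752) completed the 8 with the most pairs. The representative model of these genes may hold no sequence of its own. Where it had at least 1 specific pair in each library, 118 genes remained. By other settings, 555 genes passed in replicate 2 alone, 240 in replicate 1 alone, 517 from 20 pairs and 99 from 100 pairs. The 118 were led by the translation factor gene AT5G54940 at 99.6% of 794 and 99.6% of 3386 pairs and the 14-3-3 gene GRF1 at 99.5% of 606 and 99.5% of 2187, both chosen after their values were seen.

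Pairs were spread fairly evenly along transcripts, with a small excess toward the 3′ end. The median gene had 56.8% of its pairs beyond the midpoint of the transcript in replicate 1, over 9501 nuclear genes with 100 or more pairs, and 54.6% in replicate 2, over 11094. The interquartile ranges over genes were 50.9% to 61.9% and 47.8% to 59.8%.

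Organelle transcripts made up a small part of both libraries, and a smaller part of replicate 2. Chloroplast genes took 0.152% of pairs in replicate 1 (exact 95% interval 0.150% to 0.155%) and 0.0480% in replicate 2 (0.0470% to 0.0491%). No chloroplast transcript between ATCG00820 and ATCG01010 had a pair, and after ATCG01130 only ATCG01230 did. Genes in those ranges are therefore missing from this share and from the C positions below. Mitochondrial genes took 0.141% (0.138% to 0.143%) and 0.0539% (0.0528% to 0.0550%). Of these 14222 and 8994 pairs, ATMG01390 held 9484 and 5731, and ATMG00020 held 3804 and 2422. Most of the mitochondrial share thus came from these transcripts, neither of which was placed in a coding sequence. This share is therefore not a measure of protein-coding mitochondrial transcripts. Among 2368 C positions of organelle transcripts covered 20 times or more in each library, 1 showed at least 10% C-to-T in both. It lies in rps14, which encodes chloroplast ribosomal protein S14, at chloroplast genome position 37161 on the reverse strand of the TAIR10.1 assembly, within the coding sequence, and gives the protein change S27L. There 25 of 25 bases in replicate 1 were changed, 100% (86.3% to 100%), and 21 of 22 in replicate 2, 95.5% (77.2% to 99.9%). Such a change is the mark of organelle RNA editing, but 10 sites with other base changes passed the same threshold. From replicate 2 alone 2 sites passed and from replicate 1 alone 3, and at a coverage of 50 none did. Intervals here cover counting error only.

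The share of pairs with a mismatch was examined in gene families that are conserved between plants and fungi, and their medians lay close to that of all genes. The median nuclear gene had a mismatch in 24.7% of pairs in replicate 1 and 19.2% in replicate 2, over 4618 genes with 1000 or more summed pairs. Medians were 25.3% and 19.2% for 16 actin-related genes, 25.8% and 19.3% for 7 tubulin genes, 24.4% and 18.8% for 8 histone genes, 24.7% and 19.0% for 68 ubiquitin genes and 24.7% and 19.7% for 32 elongation factor genes. The highest shares were those of AT2G16586 at 65.1% and 45.0%, AT5G52530 at 49.96% and 46.5%, the chaperone gene BIP1 at 45.9% and 34.3% and the extensin-like gene AT2G43150 at 30.3% and 44.7%. In AT2G16586 position 355 of the transcript differed from the reference in 98.7% of 150 bases in replicate 1 and 100% of 215 in replicate 2. The most changed positions of AT5G52530, BIP1 and AT2G43150 reached 62.5% and 68.6%, 22.6% and 11.8%, and 34.8% and 41.2%.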

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

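The all-model list alone was the planned count and became an alternative after the data were seen. The tests on fragments under 150 bases, on a thinned replicate 2, with length by aligned position, with members at least 90% placeable and with the representative model seen were chosen after the data were seen. No paired analysis was possible because there is a single group. Equal splitting of reads over genes was not run. The cause of a change was not tested unless stated.

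Pearson r was 0.984 on the representative list alone, 0.992 with duplicates counted once, 0.991 without mismatches, 0.982 on the all-model list alone, 0.937 on fragments under 150 bases, 0.983 with a pseudocount of 0.1 and 0.989 for summed counts of 10 or more. The mean chi-square was 12.1 on the representative list, 6.45 with duplicates counted once, 8.53 without mismatches, 7.11 on fragments under 150 bases and 12.1 for summed counts of 10 or more. Nuclear totals and the median of ratios left both inside their intervals.

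Of the 226 genes differing between the libraries, the count became 114 on the representative list (fewer genes tested), 794 on the all-model list, 803 on fragments under 150 bases (519335 pairs in replicate 2), 388 with no count filter, 378 from 10 summed pairs and 933 at 1.5-fold. Thinning replicate 2 to the depth of replicate 1 gave 219, of which 169 were among the 226. Higher calls in replicate 2 made up 30.1%, and 39.1% under the median of ratios, but 73.4% on the all-model list and 82.6% on fragments under 150 bases (663 of 803, with 40 calls among the 226). Of the named ratios with enough pairs on those fragments, 5 lost their call and 2 kept it, and 1 lost it with duplicates counted once. Where a named ratio had a value, its sign was kept.

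Of 20 lists 15 were called, and 7 of the 12 with enough members on the representative list. There, on 3 to 5 members, the camalexin list lay at percentile 97.24, the WRKY list at 96.9 and the salicylate list at 39.09, below the random median. The ethylene list lost its call on the all-model list (5.15), by CPM (1.84) and without replicate 1 (4.77), but kept it without replicate 2 (1.69), and reversed to 99.99 from 10 summed pairs. The vascular list lost it on the all-model list (95.3) and the pollen list by CPM (1.65). The seed list gained it at a pseudocount of 0.1 (1.86) and with aligned length (0.99). Between the libraries, 0 of 11 lists were called on the representative list, where 10 of 32 photosynthesis genes had a median log2 ratio of 0.047, and 3 of 16 on the all-model list, with jasmonate at 0.21 and WRKY at -0.26.

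Genes read mainly from another model numbered 517 from 20 pairs, 99 from 100 pairs and 118 with the representative model seen, and 240 to 555 over single libraries. C-to-T sites numbered 0 at coverage 50 and 2 to 3 over single libraries. Depth limits these sites and the genes with few pairs. Among the values of named gene levels under these alternatives, 210 moved by more than the SD of the libraries and 218 did not. With duplicates counted once 59 moved and 23 did not, with aligned length 48 and 34, and on the all-model list 70 and 9. On the representative list all 23 moved. Without mismatches 10 moved and 70 did not, and with nuclear totals none of 82 moved. The SDs printed with levels therefore do not cover these choices.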

Other observations

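The tests of gene families and the genes named with them, the fragment-length tests of the higher and the lower genes taken apart and the minimum of 5 expected pairs were chosen only after the result was seen.

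Several gene families of the annotation, some of whose members are in the fixed lists, were rich in abundant transcripts. Of 51 glutathione S-transferase genes with a pair, 21 were among the top 5% of nuclear genes (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over 22 families, p = 1.2e-13), with GSTF9 at 3060 ± 688 RPKM (SD, n = 2). Peroxidases followed with 16 of 75 (exact p = 5.3e-06), led by PRX34 and by APX1 at 1597 ± 16.8 RPKM, and cytochrome P450 genes with 19 of 166 (exact p = 0.0038), among them CYP71B6 at 1115 ± 70.8. Of 319 ribosomal protein genes 89 were in the top 5% (exact p = 1.2e-40). Protein kinases were the exception, with 12 of 728 (exact p = 1.3e-05) and a median of 3.51 RPKM against 4.15 for all nuclear genes, although the receptor-like kinase gene LRR XI-23 stood at 451 ± 27.3. The median of the cytochrome P450 genes was lower still, at 2.16 RPKM, so the excess of that family lay among its most abundant members.

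Other families had single very abundant members without passing the test as a group. The legume lectin genes AT3G15356 and AT3G16530 stood at 3246 ± 263 and 3039 ± 129 RPKM (SD, n = 2), where 8 of 117 lectin genes were in the top 5%. The transporter gene ABCG40 stood at 2714 ± 255, the extensin gene EXT3 at 1815 ± 284, the chitinase gene CHI (AT2G43570) at 736 ± 169 and the transcription factor gene NAC102 at 464 ± 10.3. Genes of one family are related, so these p-values describe the libraries and not independent genes.

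The 226 genes that differed between the libraries were followed up with 3 technical explanations, and no biological one was tested because the design has a single group. Centring the ratios within 20 bins left 68.1% of the calls for transcript length (exact 95% interval 61.6% to 74.2%) and 70.8% for GC content (64.4% to 76.6%), between the bounds of 50% and 80% set beforehand. On fragments under 150 bases in both libraries the 226 genes kept 45.5% of their median log2 ratio (29.2% to 66.0%), the 158 lower in replicate 2 kept 34.7% (5.64% to 49.8%) and the 68 higher kept 95.4% (59.2% to 118%). Replicate 2 had only 519335 such pairs, so 41.1% of the lower and 25% of the higher genes had 5 or more pairs expected there. The 65 lower genes that did kept 53.8% (24.7% to 77.0%). Simulated with no change in ratio, all 158 lower genes kept 97.7% (84.2% to 114%), against the 34.7% found. No simulation was run for the 65 alone. Fragments under 150 bases were most often in the bin from 120 bases in replicate 1 and from 80 in replicate 2. Their lengths were thus not matched between the libraries, and too few pairs were left. The test therefore cannot decide whether fragment length accounts for part of the deficits, and run and library cannot be told apart.

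The organelle share was lower in replicate 2 by 1.52 on the log2 scale. Nuclear genes matched to the 33 organelle genes on transcript length had a log2 ratio of -0.045, and those matched on GC content 0.20, so neither property gave the deficit. On fragments under 150 bases in both libraries the log2 ratio was -1.79, no smaller than on all pairs, with 441 organelle pairs in replicate 2. The deficit was thus not limited to long fragments. These fragments were 99.5% of replicate 1 and 3.11% of replicate 2, most often in the bins from 120 and from 80 bases. Fragment lengths were therefore not matched, and the test cannot decide on fragment length. Other explanations, such as a difference in poly(A) selection between the library preparations, remain open as well and were not tested.

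The model-specific share among genes of the list for representative models was 16.9% in replicate 1 and 20.2% in replicate 2. Pairs of replicate 2 with fragments under 150 bases had 18.6% (exact 95% interval 18.4% to 18.8%), against 20.3% for its longer pairs. This lies at the midpoint of 18.6%. Within replicate 2 the share was thus lower on the short fragments. These were most often in the bin from 80 bases, against the bin from 120 for replicate 1. Lengths were not matched, so the test cannot decide whether fragment length gives the difference between the libraries. It cannot be told apart from other differences between them.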
